A study of Mus musculus with 30 samples.

How the data were processed

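Gene expression was measured in 30 ovaries, the left and the right ovary of 15 female C57BL/6 mice, per the labels. 7 of the mice had drunk water with 3% dextran sulfate sodium (DSS), a sulfated polysaccharide that injures the colon lining and causes colitis, for 7 days before puberty, and 8 were untreated littermates. The ovaries were collected once the mice were sexually mature. Per the labels' protocols, total RNA was extracted with TRIzol, purified on a Zymo column and made into libraries by CEL-Seq, a method that tags and sequences the 3' ends of polyadenylated transcripts. A mixture of 3 CEL-Seq primers was used for every sample, and the deposited table holds 1 column per ovary, so the 3 barcodes had already been merged. Per the submitters' processing notes, TopHat, HTSeq and DESeq2 were used with the genome build GRCm38.p5. Neither versions, the strand setting of HTSeq nor the handling of molecular identifiers is stated. Genes that overlap another gene are therefore reported as uncertain, since reads on either strand may have been counted.

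The authors deposited a non-negative signal per gene, normalized counts written to 2 decimals, which per the file headers and the values are read counts divided by 1 size factor per library. Each library's values were whole multiples of a step of its own, between 0.53 and 1.33. Dividing by that step returned whole reads for 99.92% to 100% of the genes above 0 within a tolerance of 0.0051 normalized counts. In 3 libraries the step lay within 1% of 1 and was found from the higher values. The table holds 50600 genes, of which 21274 were at 0 in all 30 libraries. The recovered reads summed to between 3095386 and 8564770 per library, with a median of 4305814, and the normalized totals lay between 4105009 and 4608158. Of the gene identifiers, 50376 (99.56%) were found in the GENCODE M21 annotation of the same build. Coordinates are printed as deposited. For protein-coding genes of the same identifier version, the deposited 3' end lay exactly 300 nt past the annotated end in 92.21% of 17814, and in 0% of 27923 other genes.

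The mouse was the replicate. For DSS against control, the normalized counts of both ovaries were averaged per mouse, and limma 3.58.1 in R 4.3.3 (trend, two-sided) was applied to log2(mean + 1) for the 14646 genes with a mean of at least 5 over the mice, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on this log2(value + 1) scale, which understates changes of low genes. Left and right ovaries were compared on the same scale per library with the mouse as a block. The difference of the DSS effect between sides was tested on each mouse's left minus right log2 difference. In total 32 gene lists, of pathways, ovarian cell types, other tissues that can be taken with an ovary, and RNA handling, were tested with camera at a preset correlation of 0.01, and beside it with camera at an estimated correlation and with fry. Srd5a1 was tested alone by an exact permutation over all 6435 splits of the mice into 7 and 8. The likeness of a mouse's ovaries was tested with 100000 one-sided permutations of right ovaries among mice of the same group, after removal of group means per gene. The spread between mice was tested two-sided over all 6435 splits, in place of the 100000 draws first planned. These tests, the gene lists and the rule for named genes were fixed before the data were examined.

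The rule named, for DSS against control, up to 10 genes per direction past the threshold, and otherwise the 5 with the smallest p in each direction as values that did not pass. It also named Srd5a1, Amh, Cyp19a1, Fshr, Lhcgr, Star, Cyp17a1 and Foxl2, and from each list described the 2 to 4 members with the smallest p. For left against right it took 5 genes per direction, and for the difference between sides 3. Some list members that the rule named are not described here. Genes named outside the rule are said to have been chosen after their values were seen.

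The gene-wise limma tests were tested on simulated data drawn from the real means and depths, with 50 genes changed at each of 4 sizes among 14646. Variation was drawn for each gene on its own. The simulation thus holds no variation shared between genes, and false calls from such variation are not covered. For DSS against control, 26% of genes changed 1.25-fold were recovered, 58% at 1.5-fold, 84% at 2-fold and 96% at 4-fold, with 11 false calls. For left against right, the shares were 42%, 76%, 92% and 100%, with 4 false calls. For the difference between sides they were 4%, 26%, 60% and 78%, with 4 false calls. These shares hold for that many changed genes at once. With fewer changed genes the adjustment is stricter, so smaller shares would be recovered. The list tests were run on a simulated list that was shifted and another that was not. The Srd5a1, likeness and spread tests and DESeq2 were not run on simulated data.

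Alternatives changed the pseudocount, the filter, the scaling (TMM factors on top, or quantile normalization), the variance model, the weights and the way ovaries were combined. Further ones used single sides, left out each mouse in turn, or used edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered whole reads. The number before the dot in a mouse's label has no stated meaning and was used as a block only as an alternative. Added after the data were seen were fits without ovaries rich in the oviduct transcript Ovgp1 (over 5000 normalized counts), fits with an oviduct score as a covariate, a correction for GC content of the last 500 nt of the transcripts, and the 2 scalings for the gene lists. Reads were recovered with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, the random effect of the mouse used statmod 1.5.0, and plots used matplotlib 3.10.9. No library was left out of the main tests, and the highest correlation of log2 values between any pair of libraries was 0.978, so no column was a copy of another.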

Results

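Transcript levels were compared in ovaries of mature mice that had, or had not, been through a bout of chemically induced colitis before puberty. 30 libraries were used: 14 from the left and right ovaries of 7 DSS mice and 16 from those of 8 control mice. Mice are named by group and by the number in the labels, as in DSS_10.4. Values are normalized counts, and errors are SDs over mice unless stated otherwise. DSS left ovaries had a mean of 4723255 ± 1753651 reads and DSS right ovaries 5012400 ± 961850 (n = 7 each), against 4090277 ± 613368 and 4274191 ± 401246 in control left and right ovaries (n = 8 each).

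The main question was whether colitis before puberty left a difference in ovarian transcripts of adult mice. The genes with the smallest p and a higher level in DSS mice were 9930111J21Rik2, a predicted GTPase of the interferon-inducible family, Thumpd1, an adaptor for tRNA acetylation, and 3 poorly described transcripts, Gm29055, Gm45792 and RP23-167J19.2. 9930111J21Rik2 was at 155 ± 23.0 in DSS mice (n = 7) and 102 ± 14.9 in control mice (n = 8), a log2 difference of 0.60 (SE 0.10), and Thumpd1 at 90.9 ± 10.62 and 61.5 ± 8.40 (log2 0.56, SE 0.10). Gm29055 measured 113 ± 18.99 and 72.2 ± 10.7 (log2 0.64), Gm45792 188 ± 26.1 and 135 ± 12.3 (log2 0.46), and RP23-167J19.2 4637 ± 1014 and 2793 ± 468 (log2 0.72). Each of these 5 genes was above the control median in 7 of 7 DSS mice, and with limma none passed adjustment over all genes, with an adjusted p of 0.0926 for all 5; edgeR (adjusted p = 0.0416 for each) and DESeq2 called all 5. The 5 genes with the smallest p and a lower level were Mpv17l2, a mitochondrial inner membrane protein, Clip2, a microtubule linker, Tiam1, an exchange factor for the GTPase Rac1, Tmem132a and Evi5l. Mpv17l2 was at 43.6 ± 3.60 in DSS mice and 56.2 ± 3.96 in control mice (log2 -0.36, adjusted p = 0.139), and Clip2 at 30.7 ± 2.58 and 40.1 ± 3.16 (log2 -0.38, adjusted p = 0.139). Tiam1 had a log2 difference of -0.44 (adjusted p = 0.262), Tmem132a of -0.33 (0.268) and Evi5l of -0.29 (0.287), each below the control median in 7 of 7 DSS mice.

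By position, 9930111J21Rik2 (ENSMUSG00000069892.9) lies on chromosome 11 at 49015574 to 49051242 on the minus strand, opposite Olfr56. Thumpd1 (ENSMUSG00000030942.8) is on chromosome 7 at 119714793 to 119720798, and Gm45792 (ENSMUSG00000108884.1) on the same chromosome at 119626519 to 119631058, antisense to Acsm1 and overlapping Gm19950. Gm29055 (ENSMUSG00000100768.1) is annotated as sense-intronic within Dis3l2, on chromosome 1 at 86774819 to 86776528. Its host Dis3l2 had a log2 difference of 0.05 (SE 0.07). RP23-167J19.2 (ENSMUSG00000112622.1) lies inside Lrriq1, on chromosome 10 at 103207748 to 103213437, and belongs to the annotation class TEC, transcripts still awaiting experimental evidence. Mpv17l2 (ENSMUSG00000035559.9; chromosome 8, 70758349 to 70760946) overlaps Rab3a on the other strand, and Clip2 (ENSMUSG00000063146.11; chromosome 5, 134489083 to 134552434) overlaps 2700029L08Rik and Gm42884. Tiam1 (ENSMUSG00000002489.15) is on chromosome 16 at 89786811 to 89980080, Tmem132a (ENSMUSG00000024736.14) on chromosome 19 at 10857522 to 10869940, opposite Slc15a3, and Evi5l (ENSMUSG00000011832.15) on chromosome 8 at 4166567 to 4211557, opposite 4932443L11Rik and Prr36. Since the strand setting of the counting is unknown, the levels of these overlapping genes are uncertain.

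With limma, 0 of 14646 genes passed the threshold of 0.05 and 5 passed 0.1. At an unadjusted p under 0.05 there were 1169 genes, 704 higher and 465 lower in DSS mice, where 732 are expected without any difference. On the recovered reads, edgeR called 6 genes, all higher in DSS mice: the same 5 and Gm42669, which was at 112 ± 26.8 against 66.7 ± 9.98. DESeq2 called 52, of which 51 were higher, including those 6, and 1, Mpv17l2, lower. Among the 52 were 31 protein-coding genes, 11 TEC transcripts and 10 of other classes. Of all 14646 tested genes, 13059 were protein-coding and 548 TEC, so TEC transcripts made up a larger share of the calls. The count rose from 0 to 13 without mouse DSS_15.1, and to 1 without mouse DSS_13.2 or without mouse control_10.5.

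Several classes of transcript that do not code for protein moved in the same direction as these genes, a comparison chosen after the values were seen. The 548 TEC transcripts had a mean log2 difference of 0.20, with 77.0% of them higher in DSS mice (exact permutation p = 0.00979, adjusted over 12 classes 0.0416), and all 7 DSS mice had a TEC score above the control median. The 62 sense-intronic transcripts were higher in 82.3% of cases (exact permutation p = 0.00466, adjusted 0.0416). With an estimated correlation these classes had an adjusted p of 0.0808. The summed counts of 1922 odorant, vomeronasal and trace amine receptor genes, which an ovary is not known to use as such, were 358 ± 51.7 in DSS mice (n = 7) and 286 ± 25.3 in control mice (n = 8; exact permutation p = 0.00389). Ribosomal RNA tags were also at higher levels, with mt-Rnr2 at 178664 ± 38675 against 119553 ± 26144 (log2 0.58) and Gm42418, which overlaps a ribosomal RNA repeat, at 15550 ± 5403 against 7744 ± 1796 (log2 0.96). Neither passed adjustment over all genes with limma (adjusted p = 0.308 and 0.139). DESeq2 called both (0.0105 and 0.00488), and without mouse DSS_15.1 limma called Gm42418 (0.0400).

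Srd5a1, the 5-alpha-reductase that turns progesterone and testosterone into their 5-alpha-reduced forms, was lower in the ovaries of DSS mice. It was at 260 ± 25.9 in 7 DSS mice and 335 ± 55.6 in 8 control mice, a fold of 0.784 (log2 -0.35, 95% interval -0.56 to -0.14). All 7 DSS mice were below the control median, and 2 control mice lay at or below the highest DSS mouse, at 292. An exact permutation test over 6435 splits gave p = 0.00963, where the smallest p possible is 0.000311. Tested among all genes with limma, Srd5a1 did not pass (adjusted p = 0.370). The left ovary alone gave 260 ± 35.2 against 361 ± 66.3 (log2 -0.46, exact permutation p = 0.00404), and the right ovary 259 ± 30.4 against 308 ± 62.6 (log2 -0.23, exact permutation p = 0.129). Without the ovaries over 5000 counts of Ovgp1 the log2 difference was -0.38 (exact permutation p = 0.004). The gene (ENSMUSG00000021594.10; chromosome 13, 69573149 to 69611442, minus strand) overlaps Gm17108 on the same strand and Nsun2 on the other, so its level is uncertain. It was fixed before the values were seen from what is known of the study's interest in it, so its test is not independent evidence where the study picked it from these ovaries.

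**Figure D1:**
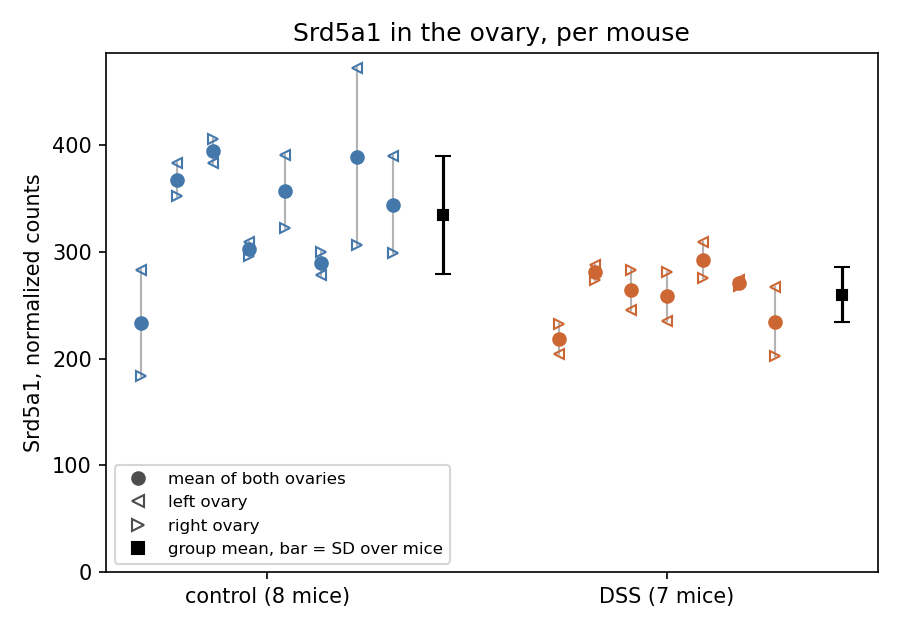
Normalized counts of Srd5a1 on a linear axis from 0, for 8 control mice (blue) and 7 DSS mice (orange). Filled circles are the mean of a mouse's ovaries, open triangles its left and right ovary, and black squares with bars the group mean and SD; group means were 335 and 260, and all 7 DSS mice lie below the control median.

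Transcripts of follicle and hormone function did not pass the test. Amh, the granulosa hormone used as a readout of growing follicles, was at 1407 ± 255 in DSS mice and 1599 ± 433 in control mice (log2 -0.15, adjusted p = 0.825). Cyp19a1, the aromatase that makes estradiol, was at 52.6 ± 21.8 and 70.4 ± 30.9 (log2 -0.44, adjusted p = 0.764), and Fshr, the FSH receptor, at 22.8 ± 7.12 and 25.5 ± 6.58 (log2 -0.18, adjusted p = 0.845). In right ovaries alone, Cyp19a1 and Fshr were higher in DSS mice (log2 0.063 and 0.18). Lhcgr, the LH receptor, had a log2 difference of 0.23 (95% interval -0.38 to 0.84) and Cyp17a1, the androgen-forming lyase of theca cells, one of 0.45 (-0.98 to 1.88). Both differences changed sign without mouse control_15.3, to -0.06 and -0.18. Star, which carries cholesterol into mitochondria, was at 4760 ± 934 against 4790 ± 1275, and Foxl2, a granulosa identity factor, at 152 ± 9.95 against 152 ± 19.6, with log2 differences of 0.02 and 0.01 whose sign depended on how ovaries were combined. Star overlaps Ash2l on the other strand, so its level is uncertain.

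The lists of steroid and cholesterol synthesis, of oocyte, granulosa, theca and luteal cells, and of reserve regulators, LH response and receptors did not pass camera. Steroidogenesis had 10 of 17 tested members lower (list adjusted p = 0.174), and only Srd5a1 fell when adjusted over the list alone, against 0 over all genes. Its next members were Fdxr (log2 -0.19) and Hsd17b1 (-0.23). Cholesterol synthesis had 11 of 20 lower (0.601). There Srebf2, the transcription factor that turns on the pathway's enzymes, fell when adjusted over the list alone, from 144 ± 13.51 in control mice to 119 ± 10.55 in DSS mice (log2 -0.28), against 0 over all genes. Oocyte genes were lower in 16 of 24 cases (0.134), led by Gdf9 (log2 -0.22) and Zar1 (-0.22), and granulosa genes in 9 of 17 (0.196), led by Amhr2 (log2 -0.27) and Hsd17b1. Ovarian reserve regulators were lower in 6 of 15 (0.286; Amhr2 among them). The LH response and ovulation list had 7 of 12 lower (0.601; Cebpb, log2 -0.23, and Pgr, 0.93), luteal genes 6 of 14 (0.601; Onecut2, 0.46, and Akr1c18, 0.51), theca and interstitial genes 3 of 7 (0.813; Nr2f2, -0.05, and Cyp17a1), and hormone and growth factor receptors 6 of 17 (0.333; Amhr2 lower and Pgr higher). In these lists no gene changed over all genes, and none changed adjusted over the list alone except Srd5a1 and Srebf2.

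With camera at its preset correlation, transcripts of immune cells and of tissues that lie against the ovary were higher in DSS mice as groups. None of these calls held with an estimated correlation (adjusted p = 0.787 with an estimated correlation for each) or with fry (smallest adjusted p = 0.447). With the oviduct score as a covariate, a fit added after the data were seen, 0 of 32 lists passed camera. How closely each group followed oviduct markers over mice was not tested. MHC class II genes, which present antigen to T cells, were higher in 7 of 7 (median log2 0.19, adjusted p = 0.00674). Ciita, their master activator, rose when adjusted over the list alone, at 21.2 ± 6.85 against 14.2 ± 2.61, against 0 genes over all genes, and H2-DMa had a log2 difference of 0.21. Interferon response genes were higher in 19 of 19 (median 0.18, adjusted p = 0.00674), among them Gbp3 at 136 ± 26.9 against 116 ± 18.8 and Rtp4 (log2 0.21). B and plasma cell genes were higher in 6 of 6 (median 0.63, adjusted p = 0.0420), with the immunoglobulin chains Ighm at 39.1 ± 42.9 against 14.96 ± 6.46 and Igkc at 120 ± 113 against 46.3 ± 39.8. T and NK cell genes were higher in 7 of 8 (median 0.33, adjusted p = 0.0420), led by Trac (log2 0.68) and Cd4 (0.45), and macrophage genes in 10 of 14 (median 0.16, adjusted p = 0.0396), led by Mrc1 (0.28) and Cx3cr1 (0.30). Adipose genes were higher in 8 of 8 (median 1.05, adjusted p = 0.0112), with Adipoq at 311 ± 334 against 156 ± 200, Pparg (log2 0.35) and Car3 (1.12). Oviduct genes were higher in 9 of 9 (median 1.08, adjusted p = 0.0211), with the ciliated cell factor Foxj1 at 23.8 ± 26.5 against 9.07 ± 13.96 and Sntn at a log2 difference of 1.78.

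Lower as groups with camera, and likewise lost with an estimated correlation (adjusted p = 0.787 for each) and with fry, were cytosolic ribosomal proteins, in 65 of 72 genes (median log2 -0.04, adjusted p = 0.00238), among them Rpl7a (log2 -0.11), and cell cycle genes, in 19 of 21 (median -0.09, adjusted p = 0.0396), led by Ccne1 (-0.39) and Mcm6 (-0.14). Thus camera called 9 of 32 lists, 7 higher and 2 lower. Among members of these 9 lists no gene passed over all genes, and only Ciita passed adjusted over the list alone. In 100 splits of the mice that include the real one, 97 others also had at least 1 list called by camera at the preset correlation. A call at this setting is therefore common without regard to treatment.

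Ovgp1, the secreted oviduct glycoprotein, ranged from 110 to 66716 counts, and 7 ovaries of 6 mice exceeded 5000: left ovaries of mice DSS_10.4 and DSS_11.2, both ovaries of mouse DSS_11.1, and right ovaries of mice control_10.5, control_13.4 and control_16.9. The first principal component over mice held 36.4% of the variance and had an absolute correlation of 0.958 with the oviduct score. Without those 7 ovaries, which leaves 6 DSS and 8 control mice, 0 of 32 lists passed camera (5 at an unadjusted p under 0.05), MHC class II genes were higher in 5 of 7, interferon genes in 12 of 19, and macrophage genes in 7 of 14. Likewise 0 lists passed without mouse DSS_10.4 or without mouse DSS_11.2, 4 passed without mouse DSS_11.1, 3 without mouse control_13.5, and 14 without mouse control_10.5. In right ovaries alone 8 of 9 oviduct genes were lower in DSS mice and 16 of 21 cell cycle genes were higher. TMM scaling kept all 9 calls, and quantile normalization kept 5, losing ribosomal proteins, cell cycle, B and plasma cells, and T and NK cells.

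**Figure D2:**
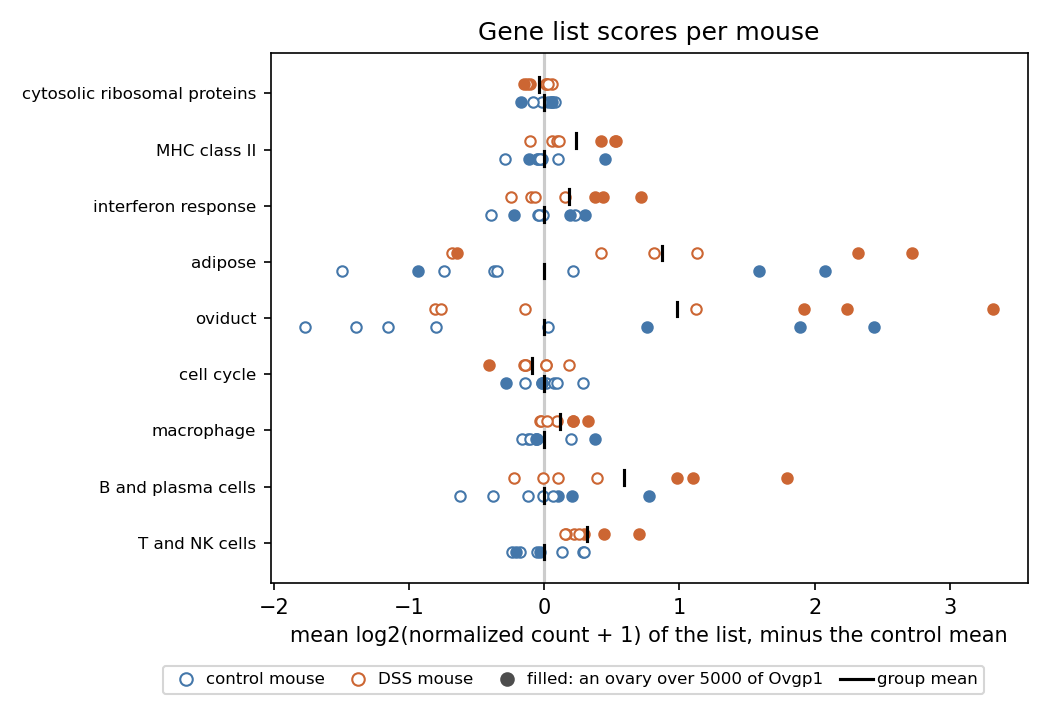
Per-mouse scores of the 9 called gene lists: the horizontal axis is the mean log2(normalized count + 1) of a list minus the control mean, with control mice in blue, DSS mice in orange and black ticks at the group means. Filled circles are the 6 mice with an ovary over 5000 counts of Ovgp1; the oviduct score differed by 0.98 between groups while its SD was 1.61 in DSS mice and 1.56 in control mice.

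**Figure D3:**
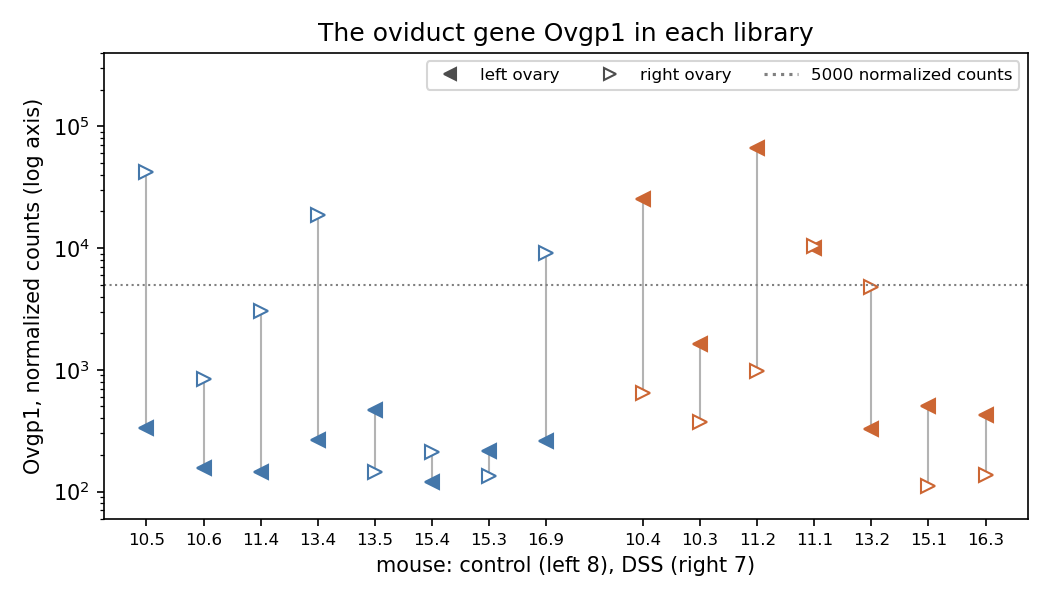
Normalized counts of Ovgp1 on a log axis in all 30 libraries, by mouse, with left ovaries as filled and right ovaries as open triangles, joined by a line within each of the 8 control (blue) and 7 DSS (orange) mice. The dotted line marks 5000 counts; values ran from 110 to 66716, and 7 ovaries lay above the line.

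The remaining lists did not pass camera; beside each stand the log2 differences of its members with the smallest p. Other tissue and cell groups were surface epithelium (10 of 13 higher, adjusted p = 0.333, Aldh1a2 -0.37 and Muc16 0.39), erythroid genes (5 of 5, 0.222, Hbb-bs 0.27 and Hbb-bt 0.27), endothelium (6 of 12, 0.4662, Eng -0.16 and Cdh5 -0.13), smooth muscle and pericytes (8 of 10, 0.195, Pdgfrb -0.20 and Rgs5 0.15), and neutrophils and mast cells (5 of 6, 0.333, Retnlg 0.99 and Cpa3 0.53). Among pathways, the extracellular matrix had 6 of 18 higher (0.4662, Col6a1 -0.12 and Tgfb1 -0.18), inflammatory cytokines and NF-kB 6 of 12 (0.813, Saa3 0.16 and Nfkbia 0.08), and DNA methylation and histone modifiers 12 of 19 (0.601), where Kdm1a, a histone demethylase, was at 56.2 ± 13.7 against 41.2 ± 6.33. Apoptosis had 6 of 16 higher (0.222, Bak1 -0.30 and Tnfrsf10b -0.20), the unfolded protein response 6 of 10 (0.601, Asns 0.16 and Sesn2 -0.12), oxidative stress 5 of 14 (0.222, Gpx4 -0.10 and Gsr -0.11) and the nuclear respiratory chain 14 of 43 (0.0887, Uqcrc1 -0.17 and Cox5a -0.12). For RNA handling, immediate early genes had 6 of 11 higher (0.601, Nr4a1 -0.45 and Ier2 -0.09) and mitochondrially encoded genes 5 of 13 (0.601, mt-Nd5 0.31 and mt-Nd4l -0.11). No member of these lists passed over all genes or adjusted over the list alone. Median, mean and test differed in sign for ovarian reserve regulators, extracellular matrix, endothelium, cholesterol synthesis, LH response and ovulation, immediate early genes, mitochondrially encoded genes, and theca and interstitial genes. Under quantile normalization the median changed sign for ovarian reserve regulators, theca and interstitial genes, endothelium, inflammatory cytokines and NF-kB, and immediate early genes.

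Left and right ovaries were compared for differences in transcript levels. The labels number left ovaries odd and right ovaries even, so a library batch cannot be told apart from the side. Genes of stratified epithelium were several-fold higher in left ovaries. Krt4 was at 118 ± 156 in left and 16.4 ± 16.7 in right ovaries (n = 15 mice, log2 2.30, SE 0.17), Krt5 at 279 ± 354 and 32.2 ± 28.0 (log2 2.37), and Sprr1a, a precursor of the cornified envelope, at 990 ± 1340 and 140 ± 152 (log2 2.31). The keratinocyte surface protein Ly6d had a log2 difference of 2.22 and the gap junction gene Gjb2 one of 1.99. The 5 genes with the smallest p that fell in left ovaries changed by less: Ndufa12, a complex I subunit, from 2147 ± 194 in right to 1531 ± 101 in left ovaries (log2 -0.49, SE 0.04), Lamp1, a lysosomal membrane protein, from 7043 ± 575 to 4787 ± 377 (log2 -0.56, SE 0.05), and adenosine kinase Adk from 529 ± 57.2 to 383 ± 44.6 (log2 -0.46). Fam160b1 (log2 -0.49) and Dync1i2, a dynein chain (-0.43), completed the 5. All 10 genes had the same direction in 15 of 15 mice, with adjusted p between 9.4e-08 for Krt4 and 7.8e-06 for Gjb2.

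With limma, 1488 of 14646 genes differed between sides, 668 higher and 820 lower in left ovaries, with a median absolute log2 difference of 0.27. There were 3464 at an unadjusted p under 0.05, where 732 are expected. Of all 14646 tested genes, 159 had the same direction in all 15 mice, which chance gives for 0.0061% of genes, and 158 of these were among the called ones. On recovered reads edgeR called 1438, of which 1419 were shared. Control mice alone gave 384 genes, of which 345 (89.8%) had the same sign in DSS mice, and DSS mice alone gave 115, of which 111 (96.5%) had the same sign in control mice, while over all tested genes 61.2% had the same sign in both groups. Both groups called 58 in common with the same sign, where independent lists would share 1.57 with the same sign. Without the 6 mice with an ovary over 5000 counts of Ovgp1, which leaves 9 mice, 733 genes passed, 623 of them among the 1488. Krt4 (ENSMUSG00000059668.5) and Krt5 (ENSMUSG00000061527.6) lie on chromosome 15 at 101918236 to 101924735 and 101706770 to 101712891, and Sprr1a (ENSMUSG00000050359.7) on chromosome 3 at 92483652 to 92485895. Ndufa12 (ENSMUSG00000020022.16) is on chromosome 10 at 94198955 to 94221743, and Lamp1 (ENSMUSG00000031447.7) on chromosome 8 at 13159161 to 13175638, opposite Grtp1. Krt5 overlaps Gm44323 and Adk overlaps Gm26372, so the levels of Krt5, Adk and Lamp1 are uncertain.

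**Figure D4:**
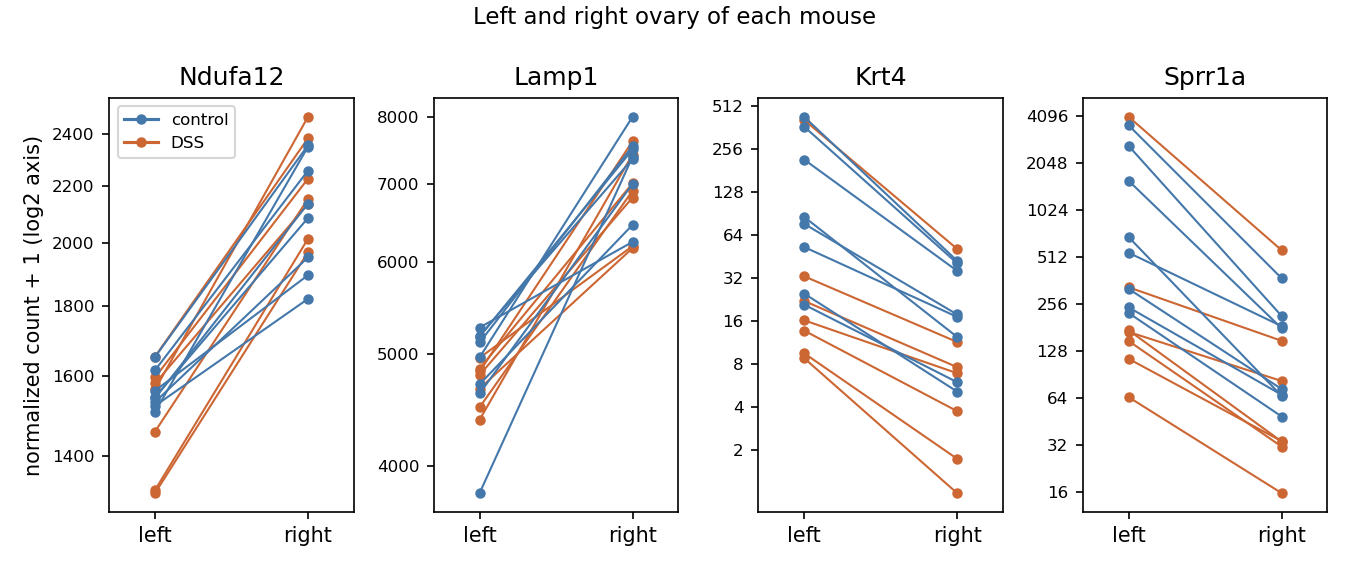
Normalized count + 1 on log2 axes of Ndufa12, Lamp1, Krt4 and Sprr1a in the left and right ovary of each mouse, 1 line per mouse, blue for 8 control and orange for 7 DSS mice. Ndufa12 and Lamp1 are lower and Krt4 and Sprr1a higher in the left ovary of 15 of 15 mice.

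Among gene lists, macrophage genes were higher in left ovaries in 10 of 14 cases with camera (median log2 0.22, adjusted p = 0.0351). The call was lost with an estimated correlation (adjusted p = 0.981 with an estimated correlation) and with fry (0.188). The complement genes C1qb (0.38), C1qc (0.34) and C1qa (0.30) and the growth factor receptor Csf1r (0.31) rose over all genes, 4 in number, and 6 rose when adjusted over the list alone. Erythroid genes were lower in left ovaries in 5 of 5 cases (median -0.54, adjusted p = 0.0351), a call also lost with an estimated correlation (adjusted p = 0.981 with an estimated correlation) and with fry (0.310). Among them was Hba-a1 at a log2 difference of -0.68 (adjusted p = 0.0390), the 1 that fell over all genes, and all 5 fell when adjusted over the list alone. Hba-a1 and Hba-a2 are near copies, so their separate levels are uncertain. Both list calls were also lost with quantile normalization (0.0503 for each), and without the mice rich in Ovgp1 the macrophage list had an adjusted p of 0.451. Tested for change in either direction, 9 lists passed fry, a test that does not compare members with other genes. Over all genes, 1488 of 14646 passed between sides. The nuclear respiratory chain had 4 genes that rose and 10 that fell of 43, and cytosolic ribosomal proteins 7 that rose, such as Rps10 (0.25) and Rpl7a (0.26), and 16 that fell, such as Rpl36 (-0.34) and Rpl10 (-0.39), of 72. Adjusted over the list alone, these became 6 and 12, and 9 and 16. Oxidative stress genes split as 4 rising, Hmox1 (0.27) among them, and 3 falling, Prdx1 (-0.33) among them, of 14. Single genes of other lists that passed over all genes included Cyp17a1 (log2 -0.52, adjusted p = 0.0188), the cell cycle inhibitor Cdkn1b (-0.68), Nr5a2 (-0.46), Ptch1 (0.38), mt-Co3 (-0.27), mt-Nd3 (-0.26) and mt-Nd4l (-0.28). Oviduct genes were higher in left ovaries in 3 of 9 cases (adjusted p = 0.957). Between sides, median and mean differed in sign for ovarian reserve regulators and extracellular matrix, and a scaling changed the sign of the median for extracellular matrix, apoptosis and ribosomal proteins.

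The effect of DSS was then set against the side of the ovary. Dcpp1, a secreted protein of the demilune and parotid family, was higher in the left ovary of 5 DSS mice and 0 control mice, with a log2 difference between groups of 4.34 (SE 1.02), and Il20rb, an interleukin-20 receptor chain, had one of 2.44 (SE 0.58). Ovgp1 itself had a difference of 4.85 (SE 1.37), as it was higher on the left in 5 of 7 DSS mice and 2 of 8 control mice; it was chosen after its values were seen. Gm26670, antisense to Rd3, had a difference of 1.14 (SE 0.26). In the other direction were the pseudogenes Gm43028 (-3.74, SE 0.62) and Rpl21-ps5 (-5.05, SE 0.96), whose reads cannot be told apart with confidence from those of related genes, and Brd1, a chromatin reader (-0.52, SE 0.12). None of these passed: with limma 0 of 14646 genes differed (smallest adjusted p = 0.103, for Gm43028), 1248 had an unadjusted p under 0.05, and edgeR called 1, Gm43028 (adjusted p = 0.000298). Leaving out 1 mouse gave Gm43028 and Rpl21-ps5 without mouse DSS_11.2, Gm43028 without mouse control_10.5 or mouse control_16.9, and Kndc1 without mouse DSS_13.2. Dcpp1 shares sequence with its neighbours Dcpp2 and Dcpp3 and overlaps Dcpp2, so its level is uncertain.

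Finally, the ovaries of a mouse were weakly alike. After group means were removed, left and right ovaries of the same mouse correlated across genes with a mean Pearson r of 0.0107, and those of different mice with -0.126 (permutation p = 0.00078, one-sided, 100000 reassignments). With side means removed as well, chosen after the values were seen, these were 0.135 and -0.0196 (permutation p = 0.00063, one-sided). Genes are not independent replicates in these correlations. The labels give the ovaries of a mouse consecutive numbers, so likeness by mouse cannot be told apart from handling in label order. Of 34 list scores, only those of stratified epithelium (r = 0.924) and pituitary (0.758) passed adjustment between a mouse's ovaries. Scores of oocyte (0.323), luteal (0.149) and granulosa genes (-0.0772) did not, in a comparison chosen after the values were seen. The spread between mice did not differ detectably between groups: the mean SD of log2 values over genes was 0.279 in DSS and 0.286 in control mice (difference -0.00651, exact permutation p = 0.860). The difference turned positive without mouse control_10.5 (0.00747) or without mouse control_15.3 (0.00716).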

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

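The tests of a library batch by side, of ciliated genes against Ovgp1, of the shared variation of keratinocyte genes with and without side means, of the LH surge in mouse control_15.3, and of other splits for genes called between DSS and control mice and for the difference between sides were chosen only after the result was seen. Also chosen then were the groups of transcripts and the comparison without ovaries rich in Ovgp1.

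Of 66 groups of values checked, 7 held a mouse far from the others of its group, where chance gives about 1 in 20. The ratio given is the gap to the nearest mouse over the range of the group. It was taken on log2 values, while the gene levels printed beside it are normalized counts. For Gm29055, mouse control_11.4 was lowest, at 50.5 against 66.6 for the next (ratio 0.539). Mpv17l2 was lowest in mouse control_15.4, at 47.1 against 54.8 (0.686), and Tmem132a in mouse control_10.5, at 99.6 against 124 (0.558). Lhcgr was lowest in mouse DSS_11.2, at 1074 against 1897 (0.771), and in mouse control_15.3, at 396 against 1688 (0.811). Cyp17a1 was lowest in mouse control_15.3, at 38.9 against 874 (0.820). The left minus right log2 value of Dcpp1 was lowest in mouse control_10.5, at -7.43 against -3.08 (0.586).

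Left and right ovaries differed in 1488 genes, among them keratinocyte genes that varied together over the 30 libraries. Their median pairwise r was 0.8347, part of which their choice fixes, but 0.816 with side means removed. RNA of stratified epithelium from 1 source would vary so. The score of 3 pituitary genes was also higher on the left in 13 of 15 mice. The second principal component over mice (11.6% of the variance) had an absolute correlation of 0.967 with the stratified epithelium score. Whether this RNA came from tissue at the ovary or from elsewhere was not tested. Bias by GC content is argued against as the whole cause of the 1488 calls, as 1475 genes were called once each library's trend was removed. So is uneven oviduct tissue, whose score was higher on the left in 9 of 15 mice. Across called genes the side difference correlated between DSS and control mice with r = 0.867 (0.0401 over all genes and 0.534 over genes called in control mice alone), but a library batch cannot be told apart from the side, since the labels number left ovaries odd and right ovaries even and these genes were picked for the difference. Anatomical difference between the sides stays open and untested. Chance can be excluded for the number of genes, as exchanging sides within mice gave at most 2 against the real 1488.

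Oviduct genes differed many-fold between ovaries, and may come from oviduct tissue carried over with single ovaries. Ciliated cell genes followed Ovgp1, a secretory cell gene, with r = 0.9465 over 30 libraries. Against the hormonal state of the whole mouse as the cause, the oviduct scores of the left and right ovary of a mouse had a Spearman rho of 0.08214 (95% interval -0.4625 to 0.5817). With group and side means removed, rho was 0.196 and Pearson r 0.0979, the latter rising to 0.431 without the 2 farthest mice. A weaker tie within mice is therefore not excluded. Whether DSS itself alters the tissue around the ovary stays open and was not tested.

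TEC transcripts were higher in DSS mice, and genomic DNA in the libraries is a candidate explanation, as summed receptor genes differed by 0.3142 on the log2 scale (95% interval 0.1253 to 0.5031). Within groups the TEC score and the receptor sum were not clearly related over mice (r = 0.311, p = 0.259, n = 15; 0.49 without the 2 farthest mice), while the TEC difference fell from 0.1975 to 0.127 with the receptor sum as a covariate. RNA of oviduct tissue is argued against, since the TEC difference was 0.2328 (0.109 to 0.3566) without the ovaries rich in Ovgp1. Sequencing depth cannot be told apart, because the difference with reads as a covariate, 0.1811, had an interval from 0.0182 to 0.3441 that holds 0.0988, the level below which depth was to count as the cause. An effect of DSS on such transcripts stays open and untested.

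Over 100 splits of the mice, only 6 called any gene between groups, the highest 355. The 100 splits, here and in each count below, include the real grouping itself. Because the real count was 0, which 100 of 100 splits reach by construction, this comparison says nothing about chance, and so does that for the difference between sides (100 of 100 splits, real 0, highest other 46). A split with many calls can arise from a structure of the mice other than treatment, which was not tested. Chance cannot be excluded for the 1169 genes at an unadjusted p under 0.05, reached by 16 of 100 splits (highest other 1716). The same holds for the 9 gene lists of DSS against control (42 of 100, highest other 20) and for the 2 lists of left against right (96 of 100, highest other 16).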

How the results depend on the processing

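Chosen only after the data were seen were the tests without ovaries or mice rich in Ovgp1, with an oviduct covariate, with GC trends removed, and the TMM and quantile scalings of the gene lists; where a result changed below, the cause was not tested, except that single sides, single groups and omitted mice leave fewer samples.

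Between DSS and control mice, the 0 genes of limma (1169 at an unadjusted p under 0.05) became 6 with edgeR, 52 with DESeq2, 11 in left ovaries only, 1 in right ovaries only, 2 with the mouse as a random effect, and 10 without ovaries over 5000 counts of Ovgp1. Leaving out 1 mouse gave 0 to 13, with 13 without mouse DSS_15.1 and 1 without mouse DSS_13.2 or mouse control_10.5. Srd5a1 stayed lower in DSS mice under each alternative run, and its call ended in right ovaries only (-0.23, exact permutation p = 0.129). The difference of the DSS effect between sides went from 0 genes to 1 with quantile normalization, 1 with robust empirical Bayes and 1 with edgeR, and to between 0 and 2 with 1 mouse left out (2 without mouse DSS_11.2).

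For left against right, control mice only gave 384 genes, DSS mice only 115, and the 9 mice without an ovary rich in Ovgp1 733, against 1488.

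The 9 lists of DSS against control became 3 in right ovaries only and 9 in left ovaries only (3 higher, 6 lower; 4 shared, without the adipose, macrophage, interferon, T and NK, and B and plasma cell lists), 0 with an estimated correlation, 0 with fry, 0 without ovaries rich in Ovgp1, 0 with the oviduct covariate and 5 with quantile normalization. Leaving out 1 mouse gave 0 (mouse DSS_10.4 or DSS_11.2) to 14 (mouse control_10.5), with 4 without mouse DSS_11.1 and 3 without mouse control_13.5. The oviduct list (adjusted p = 0.246) and the cell cycle list (0.283) reversed in right ovaries, and the macrophage list (0.926) without ovaries rich in Ovgp1. The 2 lists of left against right became 0 with an estimated correlation, 0 with fry, 4 with TMM factors and 0 with quantile normalization.

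Genes that did not pass and reversed were Star (left ovaries -0.15, random effect -0.021, mean of log2 values -0.021, array weights -0.025, omitted mice -0.088 to 0.082), Lhcgr (left -0.040, omitted mice -0.056 to 0.36), Foxl2 (left -0.36, random effect -0.033, mean of log2 values -0.033, GC trend removed -0.00188, omitted mice -0.011 to 0.060), Cyp19a1 (right 0.063), Fshr (right 0.18) and Cyp17a1 (omitted mice -0.18 to 0.83). The difference in spread ran from -0.0334 (without mouse DSS_11.2) to 0.00747 (without mouse control_10.5), also positive without mouse control_15.3 (0.00716).

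With the number before the dot as a block, 3 genes (Gm42418, 9930111J21Rik2 and RP23-167J19.2) and 1 list passed between DSS and control mice and Star was at -0.010. Srd5a1 was at log2 -0.35 (exact permutation within blocks, p = 0.0247). Whether that number pairs the mice cannot be told from these values. Of 15 mice, 5 correlated best with a mouse of their own number, a count for which no chance level was worked out. The mean r of DSS with control mice was 0.0496, -0.0428, 0.0314, 0.273 and -0.107 for numbers 10, 11, 13, 15 and 16, against -0.0109 otherwise.

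Over 34 named genes, 948 of 1008 values kept direction and side of the threshold, 37 came to pass it, 1 (Gjb2) no longer did, and 22 reversed. Over 11 lists, 110 of 228 did so, 115 no longer passed and 3 reversed. Depth limits the low genes, whose changes the log2(value + 1) scale understates.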

Other observations

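The tests of the stratified epithelium and pituitary lists, of scores within ovary pairs and of mouse control_15.3 were chosen only after the result was seen.

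Mouse control_15.3 stood apart in both ovaries in single steroid and ovulation genes, which were picked after their values were seen. Its mean level was 87.1 for Cyp11b1 against a median of 3.97 in the other 14 mice, 165 against 38.4 for Timp1 and 394 against 87.4 for Adamts1, while Hsd17b7 was at 166 against 1488 and Pappa at 6.82 against 80.4. Ovaries taken after the LH surge were tested as an explanation: 6 of 12 tested genes of the LH response and ovulation list (Adamts1, Edn2, Plat, Rgcc, Runx1 and Timp1) were above the median of the other mice in both ovaries, and Pgr, Runx2, Ptx3, Cebpb and Egr1 were below it in both. As 11 of 12 genes lay on the same side in both ovaries, 6 above is no excess by count. In size, Adamts1, Edn2, Rgcc, Runx1 and Timp1 exceeded the highest of the other 14 mice in both ovaries. Adamts1 was at 412 in the left and 375 in the right ovary, against at most 134.55 and 171.5. The list score of mouse control_15.3 was the highest of the 15 (6.48, next 6.40 in mouse DSS_10.4). Since genes moved both ways, the test leaves the LH surge open.

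In a list of stratified epithelium genes, 16 of 17 were higher in left ovaries and 14 passed over all genes (median log2 1.77), with the left score higher in 15 of 15 mice. The list was made because such genes led the left ovaries, so these values restate that observation and are no separate test of it. The mean score of DSS minus control mice was -1.70 (exact permutation p = 0.0531). Of 3 pituitary genes, 1 passed, and the left score was higher in 13 of 15 mice. Of 34 scores, 2 correlated between the left and right ovary of a mouse after adjustment: stratified epithelium (r = 0.924, rho = 0.889, adjusted permutation p = 0.00034, 0.848 without the 2 farthest mice) and pituitary (r = 0.758, rho = 0.793, adjusted permutation p = 0.0206, 0.714 without them). The unadjusted p of the former, 1e-05, is the smallest the permutations can give.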
